A study of Mus musculus with 8 samples.

How the data were processed

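MBD pull-down libraries from 4 groups of sorted mouse intestinal epithelial cells, 2 biological replicates each, were analysed from the peak lists of the authors, 1 list per library. Per the labels' protocols, 1 µg of DNA per replicate was sheared to fragments of 150 to 250 bp and enriched with the MethylMiner kit, which captures fragments by the density of their methylated CpGs. The mice were of a mixed C57BL/6 and CD1 strain. Per the submitters' processing notes, bcl2fastq 1.8.4, Bowtie 1.1.2 and SAMtools 1.2 were used and the build was mm9. Per the file headers, peaks were called with MACS 1.4.2, each library on its own and without a control library, at a p cutoff of 1e-05, with a band width of 200 bp, an effective genome size of 1.87e+09, a tag size of 180 bp and a regional background of 10000 bp. With no input or unbound library in the call, a peak is relative to other tags of its own library. Gains of copy number or repeats that collect tags can therefore be called as peaks. The tag counts per peak are whole numbers, not normalized, as the authors deposited them. The score per peak is the negative log10 of the caller's p-value times 10 and the fold is a ratio to the local background, both the authors' values per the file headers. Both were used to rank or filter peaks within a list, and the fold is also given for some of the regions named. Start, end and summit positions were used in mm9 as deposited, and the last peak on chromosome 1 ended at 197195203.

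Depth ranged from 31438314 to 55442400 tags per library, per the file headers. Because each list was thresholded on its own, a missing peak means only that the tags did not pass the caller's cutoff, and the number of peaks depends on enrichment and depth as well as on methylation. Enrichment by an MBD protein gives relative amounts of densely methylated DNA and no percent methylation per site.

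All lists were merged into regions wherever peaks shared at least 1 bp. A region was assigned to a group when every library of that group had a peak in it and no library of the group compared had one. The comparisons were E14.5 with E12.5, ISC with E14.5, enterocytes with ISC, and the 4 adult with the 4 embryonic libraries. These are counts of regions with no test over replicates. To set them against the spread between replicates, every other split of the same libraries was counted in the same way. The tag counts of peaks were not tested as counts, because they exist only where a list has a peak. Overlap of lists was given as the Jaccard index over bases, with an exact test over the 105 ways to pair 8 libraries. The share of peaks on X was compared with an exact two-sided permutation test, with 95% Wilson intervals that cover counting error only. For the presence of a group's regions in another group, regions of like strength were those in the same of 10 equal classes by the lower of the group's 2 percentiles. This reference holds all regions of the group. Regions picked for lacking peaks in the compared group were called less often than it in every other group. The sign of such a difference is therefore no evidence of a shared change.

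The rule for the regions named, set before the data were examined, took 5 per direction and comparison, ranked by the lower percentile of the best peak's score within its own list over the libraries of the group. The design also held promoters, gene lists, marker genes of other cell types and imprinted, germline and housekeeping controls. None of these was analysed here, because the gene table at hand is of GRCm38.p6 and the peaks are on mm9, and positions were not converted between builds. For the same reason peaks were not assigned to genes, exons or introns, and the X comparison used peaks in place of promoters.

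Alternatives set before the data were examined were equal-length lists (the 84990 highest-scoring peaks of each), the stricter 50% of each list by score, merging within 500 bp, presence only where peaks covered 50% of the region, a looser presence rule, and leaving out each replicate. Added later were equal-length lists ranked by fold, intervals of 100 bp either side of summits, autosomes only, regions in the top 25% of the lists of a group with no peak in the other, and E14.5 alone as the embryonic side. Also added later were scans along the 19 autosomes, with an exact one-sided hypergeometric test in 100 kb windows (250 kb as the alternative), Benjamini-Hochberg adjusted, and with the longest run of consecutive regions against 1000 shuffles. Both scans take neighbouring regions as independent, although peaks that lie close can share the caller's regional background.

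The comparison was tested on simulated data built on the 475861 regions, with 200 planted regions per direction. Of these, 150 and 159 were recovered for E14.5 with E12.5, 145 and 151 for ISC with E14.5, 165 and 155 for enterocytes with ISC, and 119 and 114 for adult with embryo. The simulation dropped and added calls at random, so the expected recovery was 77.8%, and 60.5% for adult with embryo. Each recovered number equalled that of the planted regions still present in the simulated calls. This checks the counting rule only, and neither the rate of false calls nor the power to find real changes. Analyses were run in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6.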

Results

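DNA methylation was profiled in the epithelium of the mouse small intestine by MBD sequencing, in which the methyl-CpG-binding domain of an MBD protein pulls down methylated DNA fragments before sequencing. The 8 libraries formed 4 groups of 2 biological replicates. Embryonic epithelium came from 2 stages, E12.5 and E14.5 in embryonic days, and was sorted as EpCAM-positive cells without the endothelial marker CD31 or the leukocyte marker CD45. Adult cells came from males at postnatal day 60. They were intestinal stem cells (ISC), sorted for high EGFP driven by Lgr5, a marker of the stem cells at the crypt base, and enterocytes, the absorptive cells of the villus epithelium. Each sample was a list of peaks, the stretches of the genome where pulled-down fragments piled up, in mm9 coordinates.

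The E12.5 libraries were the deepest in total tags, with 55237390 and 55442400, yet gave the shortest lists, 100314 and 84990 peaks. The E14.5 libraries had 34567645 and 34889223 tags and the longest lists, 317772 and 338262 peaks. ISC libraries had 32423813 and 31438314 tags with 203322 and 282490 peaks, and enterocyte libraries 43343543 and 39142426 tags with 164157 and 232179 peaks. Peaks held 8.65% ± 1.69 of the tags at E12.5, 33.8% ± 5.54 at E14.5, 31.3% ± 10.7 in ISC and 29.8% ± 4.61 in enterocytes (SD, n = 2 each). Median peak length ranged from 272 bp in E14.5 replicate 2 to 849 bp in enterocyte replicate 1.

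**Figure D1:**
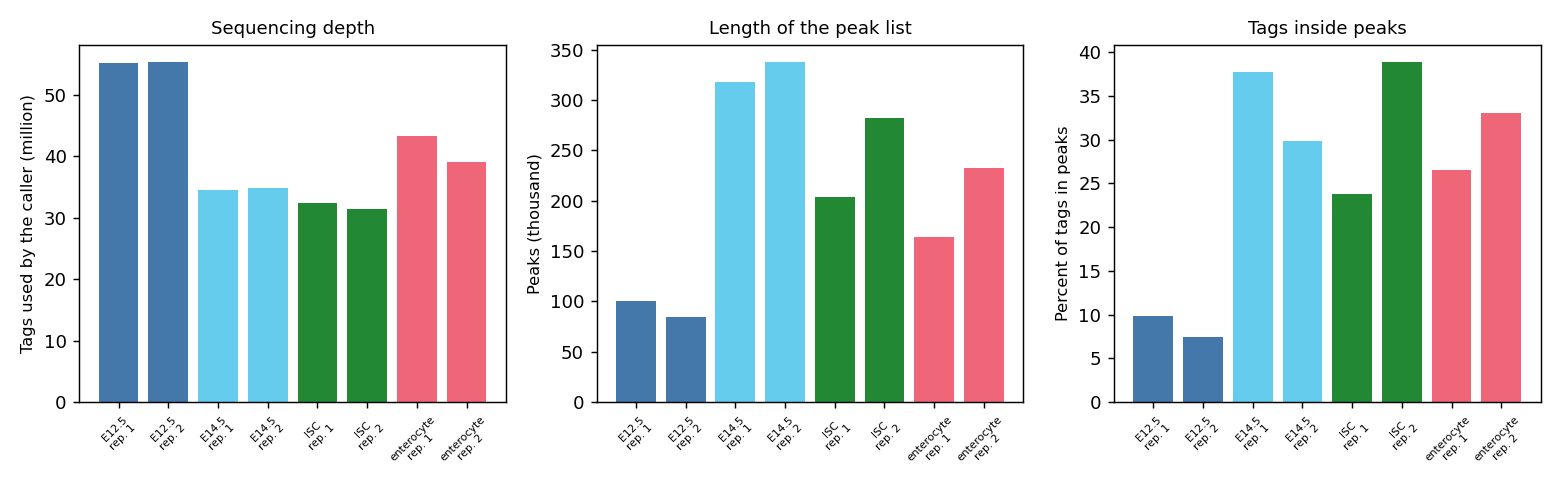
Bars give, for each of the 8 libraries, the total tags (left), the number of peaks (middle) and the percent of total tags inside peaks (right). The left axis is labelled as tags used by the caller, but shows the total per the file header. The E12.5 libraries had the most total tags, the fewest peaks, 100314 and 84990, and the lowest percent of tags inside them, 9.84 and 7.46.

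Merging all lists gave 475861 regions with a median length of 557 bp. Of these, 24563 were called in all 8 libraries, with a median length of 1225 bp, and 133930 (28.1%) in a single library. On average, replicates of a group overlapped more than libraries of different groups, with a mean Jaccard index over bases of 37.8% for the 4 replicate pairs and 30.4% for the 24 other pairs (exact one-sided permutation p = 0.0190, 2 of 105 pairings of the libraries being as high). The replicate pairs were not alike, since E12.5 replicates shared 22.2% of bases and enterocyte replicates 47.9%. E12.5 replicate 1 overlapped 5 of the 6 libraries of other groups more, the highest at 24.9%. E14.5 replicate 1 shared 49.2% with ISC replicate 2 and 38.8% with its own replicate, and ISC replicate 2 and enterocyte replicate 2 shared 51.9%. Of the 83533 regions on which the 2 replicates of every group matched, 26140 (31.3%) were called at E14.5, in ISC and in enterocytes but not at E12.5, 24563 (29.4%) in all groups and 17500 (20.9%) at E14.5 only.

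The comparison of E14.5 with E12.5 asked how methylation changed as the embryonic gut tube epithelium developed. A peak in both E14.5 libraries and neither E12.5 library was found at 113655 regions, 54.7% of the 207941 regions called in both E14.5 libraries. The opposite, a peak at E12.5 only, was found at 1314 regions, 3.48% of the 37757 called in both E12.5 libraries. Of the 113655 regions, 40.2% were also called in both ISC libraries and 34.7% in both enterocyte libraries, against 46.7% and 42.1% for E14.5 regions of like peak strength. Of the 1314 E12.5 regions, 14.7% were called in both ISC libraries, against 70.9% for E12.5 regions of like strength.

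Among single regions, 2 on chromosome 6 were strong at E14.5 and absent at E12.5. The region at 48387616 to 48389478 held 169 and 193 tags in the E14.5 replicates, and the region at 139813263 to 139814741 held 135 and 108 tags, at a fold enrichment of 9.80 and 11.4. Both were called in all 4 adult libraries too, with 118 to 195 and 93 to 131 tags. The 3 regions ranked above them, at 3049201 to 3054654 and 3055537 to 3059236 on chromosome 11 and at 2880307 to 2882764 on chromosome Y, held 838 to 2610 tags in the E14.5 libraries and had a peak of 3269 tags or more within 20 kb. A peak of 4520 tags in an E12.5 library lay 202 bp from the first of them and one of 2151 tags lay 141 bp from the Y region, while the nearest E12.5 peak to the second chromosome 11 region was 6538 bp away. In the other direction, the region at 20118658 to 20119191 on chromosome 4 held 71 and 67 tags at E12.5 and had its nearest E14.5 peak 28165 bp away, but was also called in ISC replicate 1 and enterocyte replicate 2. Regions on chromosome 9 (35100680 to 35101546), chromosome 12 (113703742 to 113704597) and chromosome 10 (43958213 to 43958813), with 57 to 80 tags, were called in the E12.5 libraries alone, and an E14.5 peak lay 762, 706 and 546 bp from them. The fifth, at 36621122 to 36622182 on chromosome 17, held 72 and 83 tags at E12.5 and was called in 3 adult libraries.

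The 114969 regions that separated the stages exceeded the 12730 given by the larger of the other 2 ways to part the same 4 libraries, and with equal lists 20282 exceeded 12311. With full lists the gap cannot be told apart from list length, since both E14.5 lists were longer than both E12.5 lists. An exact two-sided permutation test of 2 against 2 libraries cannot fall below p = 0.33, and no test over replicates was made. With each list held to its 84990 highest-scoring peaks, 12184 regions were called at E14.5 only and 8098 at E12.5 only, 26.3% and 23.6% of the regions called in both libraries of the stage. The share at E14.5 only went from 98.9% to 60.1%, and lists of equal length draw it towards balance by construction.

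**Figure D2:**
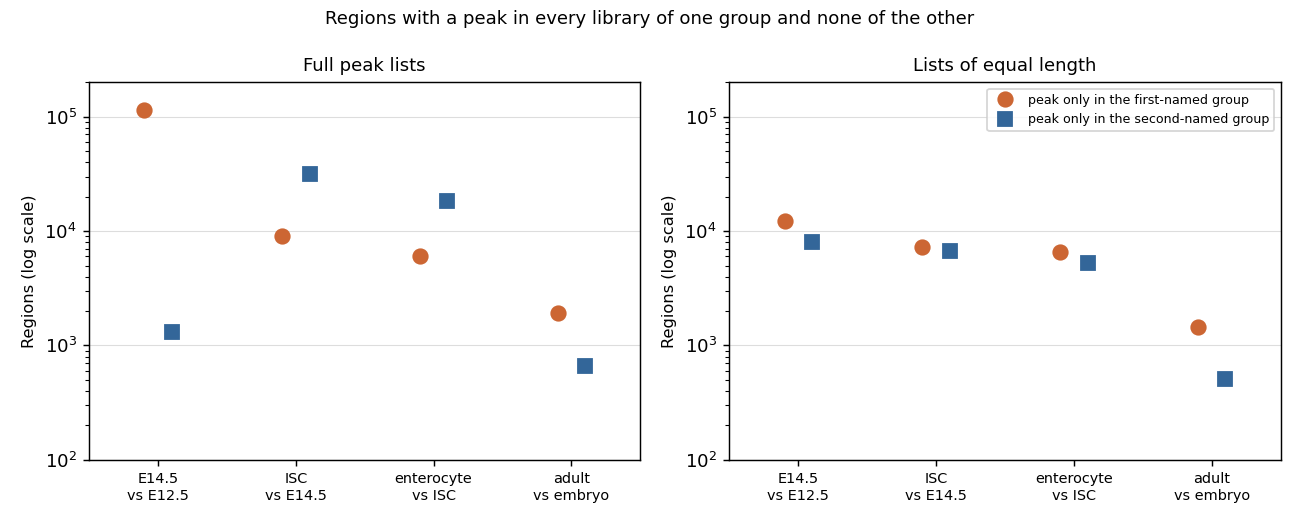
Points give the number of regions (log scale) with a peak in every library of the first-named group and none of the second (circles), or the reverse (squares), in 4 comparisons, with full lists (left) and with each list held to its 84990 highest-scoring peaks (right). With full lists ISC had fewer regions of their own than E14.5, 9088 against 31832, and with equal lists, which draw both numbers together by construction, 7313 against 6729.

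The comparison of ISC with E14.5 asked how adult stem cells differ from the fetal epithelium. A peak in both E14.5 libraries and neither ISC library was found at 31832 regions, 15.3% of those called at E14.5. A peak in both ISC libraries and neither E14.5 library was found at 9088, 6.08% of the 149516 called in ISC. Regions absent from ISC were mostly absent from enterocytes as well: 66.8% of the 31832 had no peak in either enterocyte library, against 34.8% for E14.5 regions of like peak strength. They were also more often absent from both E12.5 libraries, 79.8% against 68.1%, so absence in excess of the reference was not confined to adult cells. Of the 9088 ISC regions, 25.0% were called in both enterocyte libraries, against 46.4% for ISC regions of like strength.

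The highest-scoring ISC regions without an E14.5 peak were called in all 4 adult libraries and in no embryonic one. The region at 55926137 to 55928596 on chromosome 13 held 179 and 245 tags in ISC and 245 and 247 in enterocytes. That at 58649136 to 58652359 on chromosome 12 held 176 and 230 tags in ISC and 288 and 344 in enterocytes. The other 3 were at 127100979 to 127102253 on chromosome 10, with a fold enrichment of 10.2 and 11.6 in ISC, at 86349869 to 86352577 on chromosome 3, with 205 and 286 tags, and at 77962816 to 77963923 on chromosome 9, with 73 and 79 tags. The nearest E14.5 peak to any of these 5 lay 1777 bp away. Of the regions with a peak at E14.5 and not in ISC, that at 45815146 to 45816934 on chromosome 4 held 215 and 241 tags at E14.5, that at 14509057 to 14510239 on chromosome 17 held 123 and 126, that at 19590330 to 19591479 on chromosome 7 held 87 and 93, and that at 98434027 to 98435259 on chromosome 15 held 135 and 128. The first 3 of these were called in both E12.5 libraries too, and none of the 4 in any adult library. The Y region at 2880307 to 2882764, described above, ranked first.

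A stretch of chromosome 6 lacked adult peaks, as found by scans chosen after the data were examined. There, 10 consecutive regions called in both E14.5 libraries, from 94608148 to 94643988 (35.8 kb), had no ISC peak, while shuffling the calls along the autosomes gave a longest run of 6 in the median (permutation p = 0.00300, adjusted p = 0.0120 over the 8 directions scanned, Benjamini-Hochberg). None of the 10 had an enterocyte peak, and 6 of them had a peak in at least 1 E12.5 library. The 10 regions held 13 to 60 tags in each E14.5 library. In the window from 94600001 to 94700000, 13 of 28 regions were called at E14.5 and not in ISC, against 6.67% over all autosomal regions (exact hypergeometric test, adjusted p = 0.000175 over 23737 windows). This was the only one of those windows with an adjusted p under 0.05 for regions absent from ISC, and none passed with 250 kb windows or with lists of equal length. Equal lists keep only the 84990 highest-scoring peaks, and much of the run, at a median percentile of 53.4, drops out of them by construction.

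**Figure D3:**
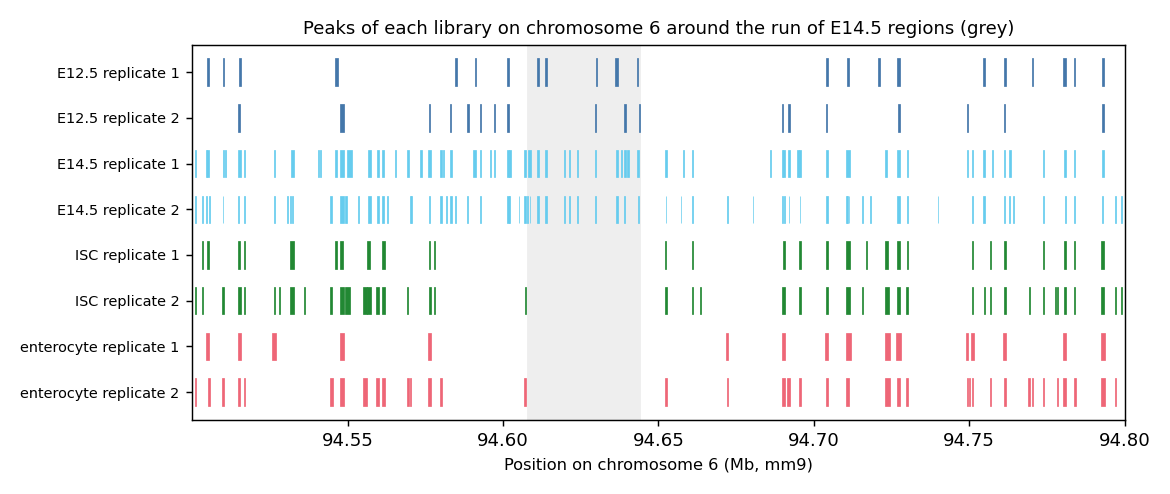
Each row is a library and each mark a peak, drawn at its position in Mb (mm9) on chromosome 6 from 94500001 to 94800000, with the run from 94608148 to 94643988 in grey. The E14.5 libraries had 12 and 10 peaks in the run and the 4 adult libraries 0, while adult peaks were present on both sides.

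The 40920 regions that separated ISC from E14.5 exceeded the 28582 of the larger of the other 2 splits of these libraries, and with equal lists 14042 exceeded 11837. Both E14.5 lists were also longer than both ISC lists, which favours the real split with full lists. With equal lists 7313 of the 49089 regions called in ISC were absent at E14.5, and 6729 of the 46296 called at E14.5 were absent from ISC. The share called in ISC only went from 22.2% to 52.1%, which equal lengths draw towards balance by construction, but it also reached 51.9% (19972 against 18495 regions) with full lists when peaks had to cover 50% of a region, so the direction depended on the presence rule. With summit intervals, which are of equal width, the share was 22.3%. E14.5 replicate 2 had the shortest peaks (median 272 bp), and whether peak width caused the shift was not tested.

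The comparison of enterocytes with ISC asked what changes as adult stem cells differentiate. A peak in both ISC libraries and neither enterocyte library was found at 18344 regions, 12.3% of those called in ISC, and the reverse at 6072, 4.61% of the 131624 called in enterocytes. Most of these peaks were weak: 0.714% of the 18344 and 1.00% of the 6072 were in the top 25% of their lists in both replicates. Of the regions called in ISC only, 42.5% were also called in both E14.5 libraries, against 63.5% for ISC regions of like peak strength, and of those called in enterocytes only, 42.0%, against 69.9%. With equal lists these shares were 21.3% and 18.2%, against 41.9% and 40.8% for regions of like strength.

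High-scoring enterocyte regions without an ISC peak were at 66518615 to 66519805 on chromosome 13, with 89 and 75 tags and called in no other library, and at 22504883 to 22505962 on chromosome 2, with 85 and 81 tags and peaks of 28 and 17 tags in the E14.5 libraries. Regions on chromosome 15, at 90975174 to 90976751 and 40859997 to 40861153, held 100 and 88 and then 84 and 64 tags in enterocytes and had peaks in both E14.5 libraries, the first in both E12.5 libraries too. The first-ranked region, at 166433383 to 166436841 near the end of chromosome X, held 998 and 1114 tags in enterocytes, and an ISC peak lay 372 bp from it, at 166437213 to 166437754, which was rank 4 among the regions called in ISC only. The other 4 of those were on chromosome 11, at 3076078 to 3080232, 3055537 to 3059236 and 3049201 to 3054654, and on chromosome Y, at 2850271 to 2858846, with 973 to 2675 tags for the chromosome 11 regions over the E14.5 and ISC libraries. An enterocyte peak of 2513 tags lay 218 bp from the last of the chromosome 11 regions.

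With full lists the 24416 regions that separated ISC from enterocytes were fewer than the 33705 that separated the first from the second replicates. They were more than the 19109 of the remaining split, and with equal lists 11737 exceeded 10783. Both first-replicate lists (203322 and 164157 peaks) were shorter than both second-replicate lists (282490 and 232179), which favours the split by replicate with full lists. In the equal lists 6518 regions were called in enterocytes only and 5219 in ISC only, 11.7% and 10.6% of the regions called in each group. The share in enterocytes only was 24.9% with full lists and 54.4% without enterocyte replicate 1, so its direction depended on that library.

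Setting the 4 adult libraries against the 4 embryonic libraries asked which methylated regions mark the adult epithelium. A peak in all 4 adult libraries and no embryonic library was found at 1911 regions, 2.03% of the 94116 called in all adult libraries, and the reverse at 662, 2.04% of the 32490 called in all embryonic libraries. Of the adult regions, 119 were in the top 25% of every adult list, and 28 of the embryonic regions were in the top 25% of every embryonic list. Apart from the adult regions on chromosomes 12, 13 and 3 given above, the highest-scoring adult regions were at 107791338 to 107793220 on chromosome 8, with 110 to 158 tags, and at 129024986 to 129026530 on chromosome 2, with 119 to 167 tags. The embryonic regions were at 167121158 to 167122277 on chromosome 1, with 66 to 112 tags, at 84718197 to 84719530 on chromosome 15, with 77 to 130, at 107472566 to 107473506 on chromosome 9, with 47 to 78, at 107332159 to 107333247 on chromosome 7, with 54 to 94, and at 21960056 to 21961123 on chromosome 6, with 86 to 112. An adult peak lay 76 bp from the chromosome 15 region and 336 bp from the chromosome 1 region.

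With lists of equal length, 1441 regions were adult only and 504 embryonic only, and the 1945 together exceeded every other split of the 8 libraries into 4 and 4, the next giving 1153. With full lists 7 of the 35 splits, the real one among them, gave as many regions as the real one. The highest of these set the 4 shortest lists against the 4 longest, so list length bears on that count. The larger number of adult regions depended on E12.5, since without E12.5 replicate 2 the adult share of the separating regions was 46.1%, and with E14.5 alone as the embryonic side it was 9.64%, against 74.3% with all libraries.

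Few peaks lay on chromosome X. Its peaks per Mb were 0.0166 to 0.0554 of the autosomal density in 7 libraries and 0.173 in E14.5 replicate 1. That library had 3669 peaks on X, 1.15% of its list (95% Wilson interval 1.12 to 1.19), against 0.372% (0.352 to 0.393) in E14.5 replicate 2 and 0.112% to 0.245% in the other 6. With equal lists E14.5 replicate 2 had 0.146%, below both E12.5 libraries (0.172% and 0.195%). Of the 4470 regions on X, 2546 were called in E14.5 replicate 1 alone. The sex of the embryos was not given in the sources used here, and the adults were males. Males carry a single X, and peak density was not corrected for copy number, so it does not show how methylated X was. The share on X averaged 0.474% ± 0.462 in embryos and 0.177% ± 0.0565 in adults (SD, n = 4 each). An exact two-sided permutation test gave p = 0.171, smallest possible 0.0286. It took the libraries as exchangeable, although those of each side were replicates of 2 groups. Without E14.5 replicate 1 the embryonic mean was 0.247% ± 0.109, and with equal lists of all libraries it was 0.300% ± 0.258, against 0.136% ± 0.0233 in adults (exact permutation p = 0.0857). Over the 4 Y regions called in all 8 libraries, E14.5 replicate 1 had 53.7 RPM (tags scaled by the library total), the lowest, and the others had 86.0 to 153. The Y peaks differed in width between libraries, from 8275 to 21252 bp in all, and per kb covered it had 6.38 RPM against 7.19 to 11.3 in the others.

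**Figure D4:**
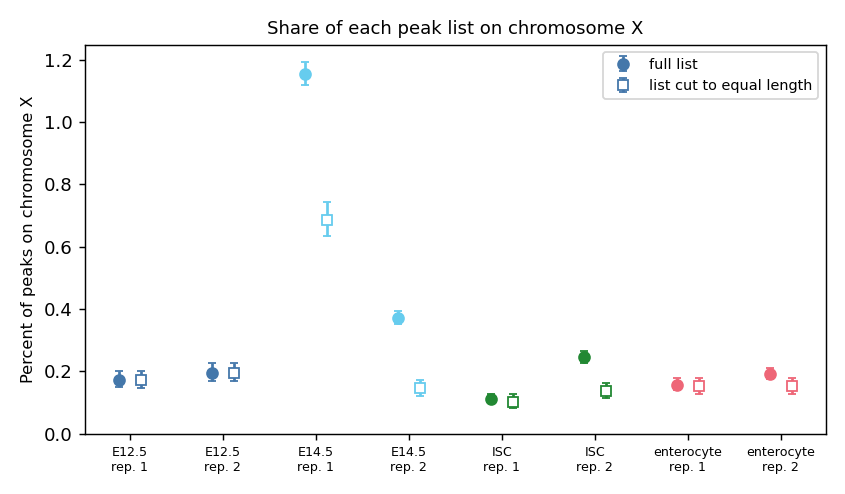
Points give the percent of peaks on chromosome X for each library, from the full list (filled) and from the list held to its 84990 highest-scoring peaks (open), with 95% Wilson intervals that cover counting error only. E14.5 replicate 1 stood at 1.15% with the full list and 0.686% with the equal list, above the other 7 libraries in both.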

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

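In the adult libraries, peaks on the mitochondrial chromosome held 13.8 RPM (tags scaled by the library total) in ISC replicate 2, far below the 40.9 to 42.5 of the other 3 adult libraries. The E14.5 libraries had 22.8 and 3.93, so a lower value occurred among the embryonic libraries. The adult value was the only one that stood apart by Dixon's test among the 16 sets of 4 libraries examined, and chance alone marks about 1 such set in 20.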

How the results depend on the processing

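The alternatives ranked by fold, from summits, on autosomes, limited to strong peaks (the top 25% of each list), with E14.5 alone as the embryonic side or with other windows were chosen after seeing the data. The causes of the shifts were not tested, except that equal-length lists remove unequal length by construction. Numbers are regions called only in the first-named and then only in the second-named group. Merging within 500 bp, summits and autosomes alone kept each count within 1.5 times and each direction. Equal-length lists gave 12184 and 8098 (60.1% first-named) for E14.5 with E12.5, 6729 at E14.5 only (52.1% in ISC only) and 5219 in ISC only (55.5% in enterocytes only), the last 2 shares being reversed, though lists of equal length draw each share towards balance by construction. Ranked by fold, such lists gave 15599 and 14488 (51.8%) for E14.5 with E12.5, 8608 at E14.5 only (51.6% ISC, reversed), 6780 in ISC only (55.8% enterocyte, reversed) and 1196 and 332 for adult with embryo. The stricter 50% of each list gave 55192 at E14.5 against E12.5, 5922 and 18065 for ISC with E14.5, 10138 in ISC only against enterocytes and 313 in embryos only. Coverage of 50% of the region gave 48305 and 3209 for E14.5 with E12.5, 19972 and 18495 (51.9%, reversed) for ISC with E14.5, 15154 in enterocytes only (46.1%) and 5970 and 278 (95.6%) for adult with embryo. The looser presence rule gave 175451 and 5267 for E14.5 with E12.5, 36322 and 94747 for ISC with E14.5, 37508 and 55400 (40.4%) for enterocytes with ISC and 26453 and 10727 for adult with embryo. Strong peaks gave 10419 and 56, 318 and 702, 61 and 131, and 119 and 28 for the same 4 comparisons. With E14.5 as the embryonic side, 21276 regions were embryonic only (9.64% adult), and with equal lists 3538 (44.3% adult), both reversed.

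Leaving out 1 library relaxes the rule, so counts grew. They ran, for E14.5 with E12.5, from 139854 to 195094 and 2726 to 12419 (91.8% to 98.6%), for ISC with E14.5 from 20606 to 38222 and 45333 to 85982 (20.8% to 45.7%, the highest without ISC replicate 1), for enterocytes with ISC from 11797 to 32822 and 27562 to 72270 (14.0% without ISC replicate 1 to 54.4% without enterocyte replicate 1, reversed), and for adult with embryo from 2051 to 5329 and 744 to 2401 (46.1% without E12.5 replicate 2, reversed, to 85.5% without E14.5 replicate 1). In each comparison and with each library left out, the count moved by over 1.5 times in at least 1 direction, except without enterocyte replicate 2 for adult with embryo. With equal lists replicate overlap was 33.8% within and 28.2% between groups (exact p = 0.0190). Of the values for single libraries and window counts under their alternatives, 15 stayed within their interval or 1.5 times and 17 moved. No paired analysis was possible because the counts come from no test, and the rule gives the same regions under any pairing. Promoter intervals, gene lists, control lists and the alternatives for count tables or normalized values were not run. Depth, from 31438314 to 55442400 total tags, and the caller's limit of 1 tag per position bear on which weak peaks could pass its cutoff.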

Other observations

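The tests in this part were chosen after the results were seen, apart from the count of splits. The adult libraries held regions that clustered on chromosome 13: with equal-length lists, 4 of 12 regions between 23500001 and 23600000 were adult only, against 0.640% of all (exact hypergeometric test, adjusted p = 0.0179), and with full lists the same scan in 250 kb windows gave 5 of 43 between 23500001 and 23750000 (exact test, adjusted p = 0.00878). Another 250 kb window, on chromosome 12 from 58500001 to 58750000, had 5 of 67 (exact test, adjusted p = 0.0407), a value no smaller than that of a window found when the first replicates of ISC and enterocytes were set against the second (100 kb, exact test, adjusted p = 0.0363). With full lists and 100 kb windows neither passed. Regions called at E12.5 only clustered on chromosome 4 between 121600001 and 121700000 (4 of 13, adjusted p = 0.000961), chromosome 5 between 14800001 and 14900000 (4 of 18, adjusted p = 0.00203) and chromosome 8 between 19900001 and 20000000 (4 of 29, adjusted p = 0.0103) in the same exact test, against 0.276% of all regions, and in 250 kb windows each of these places passed again (adjusted p of 0.000530 or less), but with equal-length lists none of these 3 windows passed and only neighbouring ones on chromosomes 5 and 8 did. In the opposite direction 19 of 28 regions on chromosome 6 between 95400001 and 95500000 were called at E14.5 and not at E12.5 (exact test, adjusted p = 0.0268), and no window passed in that direction with equal-length lists or in 250 kb. The longest run of E14.5 regions without an E12.5 peak was 36 regions on chromosome 5, from 55137731 to 57620071, where 1000 shuffles gave at most 32 (permutation p = 0.001, the smallest they can give), and with equal-length lists it was 10, on chromosome 13 (permutation p = 0.0519, adjusted p = 0.416).

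Whether the libraries separate by age was tested with all 35 splits of the 8 libraries into 4 and 4. With full lists 7 splits, the real one among them, gave at least the real 2573 separating regions, the highest 10177. That split set the 4 shortest lists (E12.5, ISC replicate 1 and enterocyte replicate 1, 84990 to 203322 peaks) against the 4 longest (232179 to 338262). Unequal lengths raise the count of such a split by construction, so full lists can neither exclude chance nor speak for it. With equal-length lists 1 split, the real one, gave as many as its 1945 regions, and the highest other gave 1153, so chance can be excluded there only if the 8 libraries are taken as exchangeable. Only 3 splits keep both replicates of every group together, too few for a test. The larger of the other 2 of these gave 675 regions with equal lists and 5588 with full lists.

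The excess of regions called at E14.5 over those called at E12.5 was weighed first. Fewer total tags at E12.5 are argued against, since the lower E12.5 total was 1.27 times the highest of the other 6. The tags left after the caller's limit of 1 per position were not counted, so lower depth after that limit stays open. Unequal list lengths cannot be told apart from a difference between the stages, since lists of equal length draw the E14.5 share, 60.1% there, towards balance by construction. What made the E12.5 lists short stays open. The highest E12.5 percent of tags in peaks was 0.414 of the lowest of the other 6 libraries, and weaker pull-down cannot be told apart from less methylated DNA at E12.5, since both libraries of the stage share it and no control library was analysed here.

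The excess of X peaks in E14.5 replicate 1 was weighed next, with no correction for the copy number of X. A longer list is argued against, since its X share was 3.10 times that of E14.5 replicate 2, whose list is longer. Stronger enrichment alone is argued against too, since its X share was 4.71 times that of ISC replicate 2, the library with the highest percent of tags in peaks. Cells from female embryos, whose inactive X is methylated at CpG islands, cannot be told apart from other causes, since its Y tags, in RPM per kb covered, were 0.793 of the median of the other 7 libraries, and its 6.38 lay close to the 7.19 and 7.46 of the enterocytes and the 7.28 and 8.05 at E12.5, but far below the 11.3 and 10.4 of ISC, from males like the enterocytes, and the 11.0 of E14.5 replicate 2. Peak width does not account for the gap to ISC replicate 2 and E14.5 replicate 2, whose Y peaks covered 8275 and 8400 bp against its 8410, but the comparison rests on 4 Y regions in 1 library and the ratio was 0.515 without division by the covered length, and no library stated to be female was analysed.

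The run on chromosome 6 without adult peaks was weighed last. An accidental string of missed calls, each independent of the next, is argued against by the enterocyte libraries, which took no part in finding the run: none of its 10 regions had a peak there, and as many regions without an ISC peak, drawn at like E14.5 strength, would all lack one with an exact p of 0.00534. Weak E14.5 peaks are argued against by shuffling within 10 classes of peak strength (permutation p = 0.00500), the median percentile in the run being 53.4 against 46.9 for all E14.5 regions. Both tests take neighbouring regions as independent. Peaks this close can share a regional background of 10000 bp, so missed calls that cluster locally cannot be excluded. A deletion in the adult mice, which would also leave 0 adult peaks in the run, cannot be told apart from a loss of methylation, since a peak list holds no tags outside peaks. The hypothesis of less methylation there in the adult epithelium rests on full lists, and with equal-length lists the longest run of E14.5 regions without an ISC peak was 5, on another chromosome. Those lists keep only the 84990 highest-scoring of the 317772 and 338262 E14.5 peaks. Much of the run, at its median percentile of 53.4, drops out of them by construction, so they cannot decide the question. The E14.5 libraries also had more peaks in the run than the chromosome average, so an embryonic excess is part of the contrast.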
